A study of Danio rerio with 17 samples.

How the data were processed

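Liver RNA from 17 zebrafish was hybridised to Affymetrix zebrafish arrays, 1 array per fish, and the study crossed sex with 0% or 25% dietary carbohydrate. The deposited table holds 1 expression value per probe set and array, and the authors' values are log2 signals already normalized between arrays; the base was inferred from the range of the values, 1.82 to 14.38. The submitters' processing notes name MAS5, RMA, GCRMA and PLIER without saying which made the table, and probe-level intensities were not analysed here. The number of arrays limits the precision, and array data give no counts behind a value.

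Of 15617 probe sets 115 controls were left out and 15502 were tested. Gene symbols came from the platform annotation: 10795 probe sets carried 1 symbol, 135 carried several and 4572 were unnamed, and 10711 of the 1-symbol probe sets were matched by Entrez ID, with 1 symbol updated. They covered 8793 symbols, 1539 of them with more than 1 probe set. No probe set names vtg1, gck or fasn alone, so these genes have no value here. Array medians spanned 0.09, under the 0.2 that would have called for quantile normalization, so the deposited values were used as they stood.

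Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the means of the 4 groups in a single fit of the 17 arrays. The 7 contrasts were sex averaged over diets and at each diet, diet in females, in males and averaged over sexes, and the interaction. P values were adjusted by Benjamini and Hochberg over the 15502 probe sets, with a threshold of 0.05. Differences are female minus male or 25% minus 0%, and the interaction is the female diet difference minus the male one. The 29 gene lists were tested per contrast with limma's camera at an inter-gene correlation of 0.01, with the brightest probe set for each gene, adjusted over the lists. Lists with under 5 measured genes would have had no test. Camera was also run with an estimated correlation, and fry, which asks whether a list's genes move on balance one way without comparing them to other genes, was run as an alternative. Camera and fry called 18 and 9 lists for sex, 8 and 2 for diet in females, 10 and 1 for diet in males, and 9 and 2 for the interaction. In none of the called lists of those 4 contrasts did median, mean and test differ in sign.

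The lists covered yolk and oestrogen response, secreted hepatocyte proteins, and pathways of metabolism, protein synthesis, stress, the clock and hormones. They also held markers of ovary, testis, exocrine and endocrine pancreas, intestine, red cells, leukocytes, stroma and muscle. The genes named in the text follow a rule: among probe sets with 1 symbol past the threshold, the 5 highest and 5 lowest differences of a contrast and up to 2 rising and 2 falling members of each list, with esr1 and pck1 always given. The contrasts, tests, lists, naming rule and the alternatives, except those said otherwise, were chosen before the data were examined.

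Alternatives were quantile normalization, centring each array on its median, the brighter part of the probe sets, eBayes with trend and robust settings, array weights, only the groups compared, the mean of a gene's probe sets, and leaving out each fish in turn. Chosen after seeing the data were leaving out male fish 11, 52 and 66, the ovary marker mean as a covariate, and the ovary, intestine and pancreas marker means as covariates. Agreement of the diet differences was tested with an exact permutation of the male diet labels over 35 splits.

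The model was tested on simulated data with known changes of 0.5, 1 and 2 on the log2 scale. It recovered 70.1%, 92.5% and 100% for the averaged sex contrast, 55.2%, 94.0% and 98.5% for diet in females, 25.4%, 73.1% and 98.5% for diet in males, and 10.4%, 71.6% and 92.4% for the interaction. False calls were 4.37%, 2.37%, 2.24% and 4.92% of the calls. The simulated noise was independent between probe sets. These rates thus leave out structure that probe sets share on real arrays, such as tissue carried over with the sample.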

Results

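Liver RNA of 17 zebrafish was measured on arrays, with 1 array per fish, in a crossed design of sex and dietary carbohydrate (0% or 25% of the diet). Per the labels the groups held 5 females on 0% (fish 7, 8, 10, 25 and 27), 5 females on 25% (fish 3, 20, 24, 49 and 51), 4 males on 0% (fish 11, 26, 30 and 66) and 3 males on 25% (fish 52, 53 and 54). The series description gives the male numbers the other way round, 3 on 0% and 4 on 25%, and the labels were followed here. Array medians lay between 3.51 and 3.60 on the log2 scale, and arrays of one group correlated at 0.925 to 0.981. The table holds no detection calls, so values near or below an array's median were not shown to be above background, and the size of a difference from such values is not exact. Values below are log2 differences ± standard error from the model, and p values are adjusted over 15502 probe sets or over 29 gene lists.

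Female and male livers were compared to ask how the hepatic transcriptome differs between the sexes. Yolk protein genes were higher in females: vtg3 by 8.90 ± 0.25, vtg2 by 8.40 ± 0.51 and vtg4 by 7.57 ± 0.30 (10 females, 7 males). Each of these genes encodes a vitellogenin, the egg yolk precursor that the liver secretes under oestrogen. Nots (nothepsin, an aspartic protease of the female fish liver) lay between 10.04 and 11.43 in females and between 3.37 and 4.25 in males, and esr1, the oestrogen receptor gene, was higher by 4.22 ± 0.14 (adjusted p = 2.49e-11). For esr1 and vtg2 all 10 females lay above all 7 males. The sizes of these differences are not exact. Male values lay below the array's median on 7 of 7 arrays for esr1 and 5 of 7 for vtg3, and in 4 of the 7 males vtg2 and vtg4 were at most 4.61 and 4.32. Male fish 11, 26 and 30, all on 0%, stood higher. Their vtg2 values were 9.39, 5.721 and 6.451, and their vtg4 values 7.083, 4.66 and 5.539. Vtg2 in females on 0% lay between 13.77 and 13.93, close to the highest values of the arrays (13.96 to 14.38). Of the 7 measured genes of yolk and oestrogen response, 5 rose and 2 did not pass (6 adjusted over the list alone). The list's adjusted p was 5.82e-14, and 0.00263 with an estimated correlation. Across all genes 2106 probe sets passed, 1243 higher and 863 lower in females, of which 206 and 107 differed at least 2-fold. The majority of higher calls was not kept with each array centred on its median (1064 higher and 1071 lower). Among the brighter probe sets 845 were higher and 797 lower, and under quantile normalization 1199 and 709.

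Genes of protein synthesis were higher in females as a group. Among 73 ribosomal protein genes 64 rose (65 adjusted over the list alone), including rpl22l1 by 0.85 ± 0.10 and rps27.2 by 0.70 ± 0.10. Their median was 0.33 (adjusted p = 3.23e-35, and adjusted p = 0.07 with an estimated correlation). Of 70 genes for folding and export in the endoplasmic reticulum 19 rose and 2 fell (21 and 2 adjusted over the list alone). The list's adjusted p was 0.00153, and adjusted p = 0.481 with an estimated correlation. Xbp1, a transcription factor of the unfolded protein response, rose by 1.61 ± 0.15 and lman1, a cargo receptor, by 1.54 ± 0.27. Sec23a, a coat protein, differed by -0.78 ± 0.17. Ovary and oocyte markers were also higher in the female liver samples: 16 of 17 rose (16 adjusted over the list alone). The egg coat genes zp2.6 at 3.33 ± 0.45 and zp3a.1 at 2.53 ± 0.27 led them (list adjusted p = 3.18e-16, and adjusted p = 0.0921 with an estimated correlation). With them rose 23 of 44 cell division genes (29 higher and 1 lower adjusted over the list alone). The cyclin ccnb1 stood at 2.16 ± 0.20, with 4 of 7 males below the array's median as against 7 of 7 for zp3a.1 (list adjusted p = 1.91e-12, and adjusted p = 0.0921 with an estimated correlation). Of 16 testis and germ cell markers 4 rose (5 adjusted over the list alone). Ccna1, a germ cell cyclin, stood at 1.70 ± 0.18 (list adjusted p = 0.00103, and adjusted p = 0.176 with an estimated correlation). For these ovary, cell division and germ cell genes, oocyte RNA carried over with the tissue could not be told apart from liver expression. Females on 25% stood highest: ccnb1 averaged 4.40 and 6.95 in females on 0% and 25%, against 3.51 and 3.53 in males. Zp3a.1 averaged 3.96 and 7.01 against 2.95 and 2.96.

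Several metabolic groups were lower in females. Me1, the cytosolic malic enzyme that makes NADPH, differed by -2.38 ± 0.39, the cytochrome P450 gene cyp2k22 by -3.77 ± 0.64, and the complement inhibitor gene cd59a by -3.21 ± 0.64. Another P450 gene, cyp2k6, ran the other way at 5.60 ± 0.27. The lower side of both cd59a (means of 3.06 and 2.96 in females) and cyp2k6 (3.91 and 2.79 in males) was also near or below the array medians. Gluconeogenesis genes fell in 5 of 11 cases (6 adjusted over the list alone). Pck2 stood at -0.71 ± 0.16 and pck1, the cytosolic phosphoenolpyruvate carboxykinase, at -2.33 ± 0.71 with 6 of 10 females below the array's median (list adjusted p = 0.00277, and adjusted p = 0.176 with an estimated correlation). Amino acid catabolism had 8 of 47 lower and 1 higher (10 and 1 adjusted over the list alone). Got1, an aspartate aminotransferase, stood at -1.31 ± 0.27 and cth at -1.32 ± 0.27 (list adjusted p = 0.00277, and adjusted p = 0.481 with an estimated correlation). Secreted hepatocyte proteins had 8 of 32 lower (9 adjusted over the list alone). The apolipoprotein genes apoeb and apoa1a stood at -1.15 ± 0.23 and -0.79 ± 0.14 (list adjusted p = 0.000182, and adjusted p = 0.466 with an estimated correlation). Oxidative phosphorylation had 10 of 90 lower and 1 higher (10 and 1 adjusted over the list alone). Sdhb, a succinate dehydrogenase subunit, stood at -0.72 ± 0.17 (list adjusted p = 0.00015, and adjusted p = 0.481 with an estimated correlation). The insulin and growth hormone axis had 5 of 24 lower (7 adjusted over the list alone). Igf1 stood at -1.32 ± 0.39 and igf2a at -1.69 ± 0.53 (list adjusted p = 0.00843, and adjusted p = 0.466 with an estimated correlation). Complement and acute phase genes had 2 of 20 lower (5 adjusted over the list alone; adjusted p = 0.00277, and adjusted p = 0.189 with an estimated correlation). The proteasome had 5 of 50 lower (0 adjusted over the list alone; adjusted p = 0.00162, and adjusted p = 0.481 with an estimated correlation).

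Lists with few members past the test also shifted towards males. Fatty acid oxidation had 1 of 29 lower and 0 adjusted over the list alone (adjusted p = 0.0166, and adjusted p = 0.49 with an estimated correlation). Xenobiotic and steroid metabolising enzymes had 4 of 49 lower and 2 higher in both counts (adjusted p = 0.0423, and adjusted p = 0.466 with an estimated correlation). Stromal markers had 1 of 22 higher and 1 lower in both counts (adjusted p = 0.0301, and adjusted p = 0.466 with an estimated correlation). Muscle markers had 1 of 27 lower in both counts (adjusted p = 0.0143, and adjusted p = 0.49 with an estimated correlation). Intestinal epithelium markers had 0 of 16 past in both counts and a median of -1.23 (adjusted p = 0.00643, and adjusted p = 0.469 with an estimated correlation). The intestinal list averaged 7.39 in fish 11, 6.74 in fish 66 and 7.33 in fish 52, all males, and at most 4.60 on every other array. Among other cell types, lists that did not pass averaged over the diets were exocrine pancreas (adjusted p = 0.603), endocrine pancreas (0.926), red blood cells (0.15) and leukocytes (0.297). Among pathways they were glycolysis (0.167), fatty acid and triglyceride synthesis (0.605), the pentose phosphate pathway (0.876), cholesterol synthesis (0.988), bile acids (0.0728), the circadian clock (0.513) and heat shock (0.242). Within the red cell list 1 of 15 rose and 1 fell in both counts, both of them haemoglobin genes: hbae3 stood at 0.43 ± 0.09 and hbba2 at -3.17 ± 0.62. Within lipid synthesis 2 of 20 rose and 3 fell in both counts, and mid1ip1l, a regulator of lipogenesis, was higher by 1.42 ± 0.21.

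Without male fish 11, 52 and 66, an alternative chosen after seeing the data, 1453 probe sets passed with 640 higher and 813 lower. Among the genes named above, sdhb (adjusted p = 0.086), sec23a (0.0602) and pck1 (0.16) did not pass there, nor did the stromal (0.109) and xenobiotic (0.0931) lists, and the muscle (0.764) and intestine (0.597) lists turned. Of the genes named above, pck1, igf1 and igf2a lost their calls in 12, 12 and 13 of the 17 fits that each left out 1 fish (highest adjusted p 0.0934, 0.089 and 0.118). Further genes that met the naming rule lost theirs too, among them stard4 in 15, fgfr4 in 14 and pgd in 13 of these fits. The muscle (0.478) and intestine (0.0662) lists lost theirs without male fish 52, and insulin and growth hormone (0.0512) without male fish 54. Fatty acid oxidation lost its call without male fish 26, 30 or 54 (highest adjusted p 0.0953), stromal markers without female fish 25 or 24 or male fish 11 (0.118), and xenobiotic enzymes in 6 of 17 such fits (0.103).

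**Figure D1:**
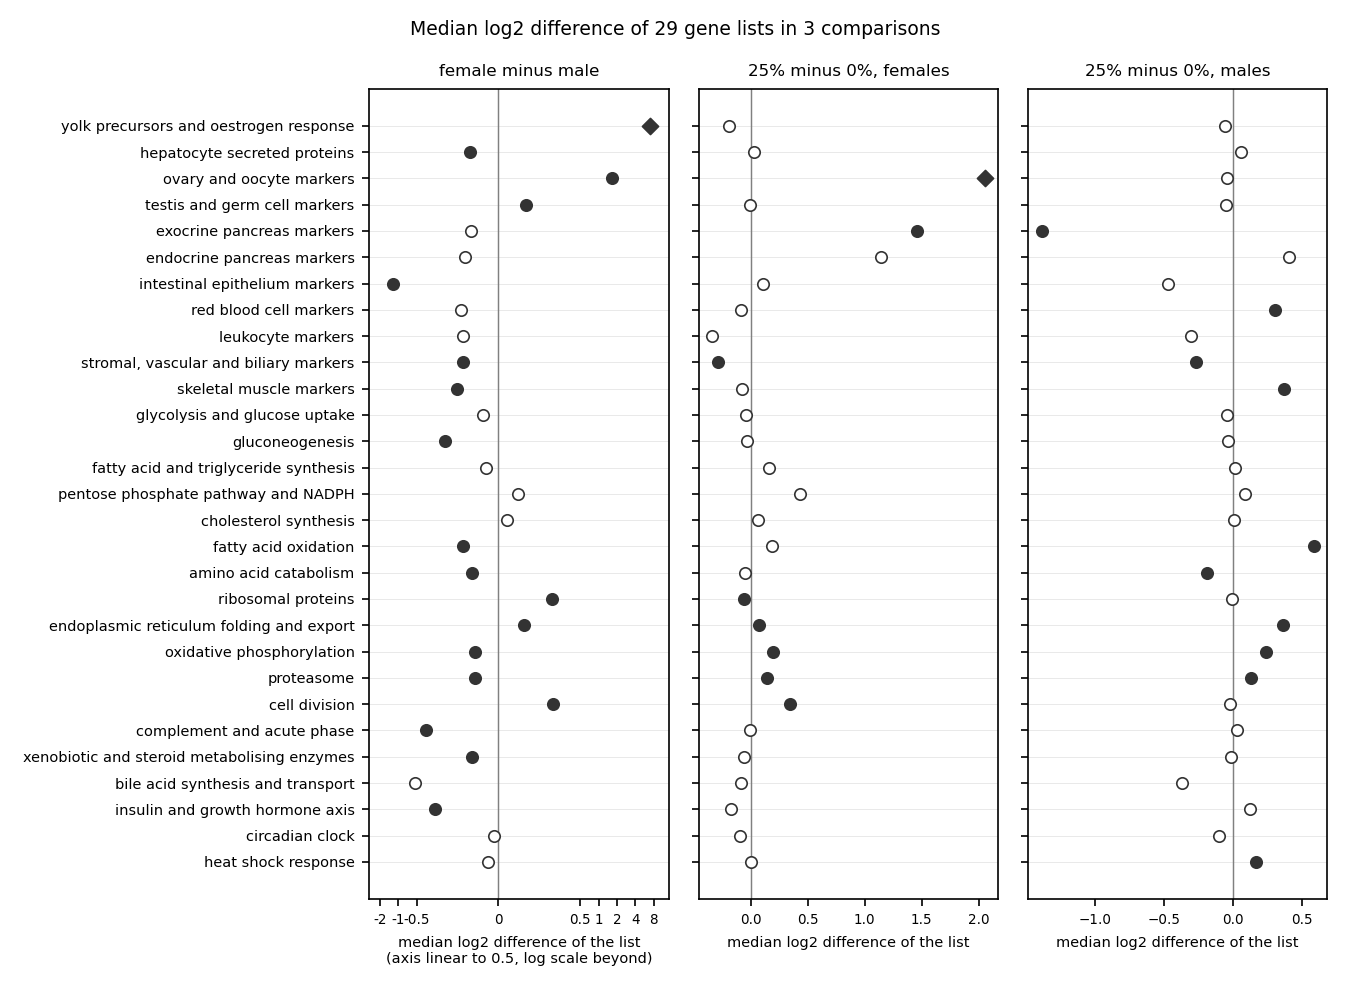
Median log2 difference of each of 29 gene lists (horizontal axis) for female minus male, 25% minus 0% carbohydrate in females, and 25% minus 0% in males. Filled symbols passed camera's test, diamonds also passed with an estimated correlation (yolk genes by sex, and ovary markers by diet in females at 2.05), and the first panel's axis is linear to 0.5 and logarithmic beyond.

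Within each diet the yolk genes again stood apart: 5 of 7 rose in females at 0% and 5 of 7 at 25%, with list medians of 6.99 and 7.02. The oestrogen receptor gene esr1 was higher in females by 4.50 at 0% and by 3.94 at 25%. Ribosomal protein genes rose in 52 of 73 cases at 0% and 34 of 73 at 25% (adjusted p = 1.31e-39 and 4.91e-27, and adjusted p = 0.0469 and 0.0794 with an estimated correlation). The list's mean differed less between diets than these counts: 12.24 in females and 11.88 in males at 0%, and 12.19 and 11.88 at 25%. Ovary markers rose in 0 of 17 cases at 0% (median 0.56, adjusted p = 0.000284, and adjusted p = 0.499 with an estimated correlation). At 25% they rose in 15 of 17 (median 2.75, adjusted p = 7.1e-26, and adjusted p = 0.0299 with an estimated correlation). Endoplasmic reticulum genes rose in 17 of 70 cases at 0% (adjusted p = 1.07e-09, and adjusted p = 0.325 with an estimated correlation) and 3 of 70 at 25% (adjusted p = 0.724). Cell division genes rose in 2 of 44 cases at 0% (2 adjusted over the list alone; adjusted p = 0.00332, and adjusted p = 0.499 with an estimated correlation). At 25% they rose in 20 of 44 (29 adjusted over the list alone; adjusted p = 4.67e-19, and 0.0299 with an estimated correlation). Testis and germ cell markers rose in 0 of 16 cases at 0% (adjusted p = 0.0291, and adjusted p = 0.498 with an estimated correlation) and 3 of 16 at 25% (adjusted p = 0.000544, and adjusted p = 0.172). Amino acid catabolism fell in 6 of 47 cases at 0% (adjusted p = 0.000146, and adjusted p = 0.498 with an estimated correlation), and at 25% 1 was lower and 1 higher (adjusted p = 0.136). Intestinal markers were not called at 25% (0.054). Exocrine pancreas, not called on average, was lower in females at 0% (median -1.55, adjusted p = 0.000716, and adjusted p = 0.512 with an estimated correlation) and higher at 25% (adjusted p = 0.0308, and adjusted p = 0.692), with 0 of 20 past at either diet. Red cells were called lower at 25% (median -0.51, adjusted p = 0.00749, and adjusted p = 0.525 with an estimated correlation) and bile acids at 0% (median -0.51, adjusted p = 0.0277, and adjusted p = 0.289 with an estimated correlation). Fatty acid oxidation (0.534), the insulin and growth hormone axis (0.122), muscle (0.713) and stromal markers (0.0773) were not called at 0%, and xenobiotic enzymes at neither diet (0.0899 and 0.0876). The interaction, which tests the difference between the diets, was not called for the testis list (adjusted p = 0.062), insulin and growth hormone (0.083), intestine (0.747), stroma (0.748) or xenobiotic enzymes (0.93). Nor was it called for bile acids. At 0%, 516 probe sets passed (352 higher, 164 lower), and at 25%, 761 (550 higher, 211 lower). Of these 139 were higher at both diets, against 12.5 for unrelated lists, 47 were lower at both, against 2.23, and 0 changed in opposite directions. The contrasts at the 2 diets share each probe set's spread in the single fit, so 12.5 and 2.23 are not exact expectations. The count at 0% fell to 290 without female fish 7, 275 without female fish 8, 307 without male fish 11 and 320 without male fish 66.

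The effect of 25% carbohydrate in females asks how the female liver samples differed between the diets. For the called probe sets as a whole, oocyte RNA carried over with the tissue could not be told apart from a response of the liver itself. With the ovary marker mean as covariate 0 probe sets passed, though that mean follows the diet. Among the named genes the largest rises were those of the egg coat gene zp2.6 by 3.25 ± 0.58, me1 (the malic enzyme) by 3.10 ± 0.50, tmsb5 by 3.05 ± 0.36, the egg coat gene zp3a.1 by 3.04 ± 0.34 and zpax1 by 3.00 ± 0.41 (5 and 5 fish). For tmsb5 and zp3a.1 3 of the 5 fish on 0% lay below the array's median, so these 2 sizes are not exact. Of 17 ovary markers 13 rose (14 adjusted over the list alone), with a median of 2.05 (adjusted p = 1.28e-27, and 0.0474 with an estimated correlation). The list's mean per fish was 3.92 ± 0.51 (SD, n = 5) on 0% and 5.68 ± 0.34 (SD, n = 5) on 25%, with all 5 fish on 25% above all 5 on 0%, while males averaged 3.37 and 3.31. Cell division genes rose in 13 of 44 cases (24 higher and 1 lower adjusted over the list alone), including ccnb1 by 2.55 ± 0.25 and ccnb2 by 1.81 ± 0.21 (adjusted p = 1.55e-16, and adjusted p = 0.0708 with an estimated correlation). For me1 (adjusted p = 0.00175) all 5 fish on 25% lay above all 5 on 0%. Me1 was also high in males, whose ovary markers were low: 8.615 to 9.46 on 0% and 9.557 to 11.089 on 25%. The male difference did not pass. High me1 thus occurred without high ovary markers.

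**Figure D2:**
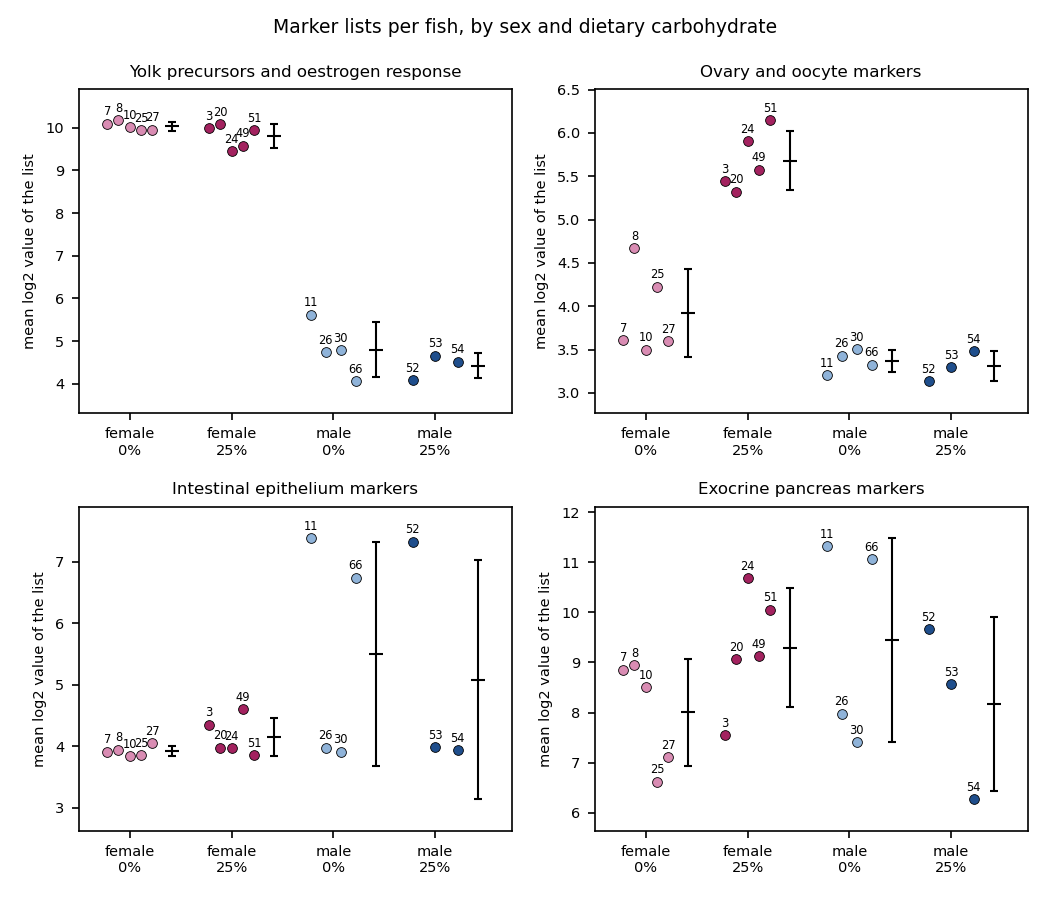
Mean log2 value of the yolk, ovary, intestine and exocrine pancreas marker lists for each fish (points, with fish numbers) by group, with black bars for the group mean ± SD. Females on 25% lay between 5.32 and 6.14 for the ovary list, and fish 11, 52 and 66 lay at 6.74 to 7.39 for the intestine list.

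In females 325 probe sets passed, 295 higher and 30 lower. Lower genes included anxa4 at -0.96 ± 0.24, ppm1la at -0.77 ± 0.18 and fbp1a, a fructose bisphosphatase of gluconeogenesis, at -0.68 ± 0.15. Fbp1a and mdh1aa (-0.52 ± 0.12) were the 2 of 11 gluconeogenesis genes that fell (2 lower and 1 higher adjusted over the list alone; list adjusted p = 0.36). Tpi1a, a glycolytic isomerase, rose by 0.52 ± 0.09, from below the array's median in 4 of 5 fish on 0%, and was the 1 of 28 glycolysis genes that passed. The oestrogen receptor gene esr1 stood at -0.52 ± 0.18 (adjusted p = 0.204) and pck1 at 1.36 ± 0.91 (adjusted p = 0.576). The yolk list had 0 of 7 past in both counts (median -0.19, adjusted p = 0.197). Lists with 0 members past in both counts also shifted. Oxidative phosphorylation moved upwards (median 0.19, adjusted p = 8.12e-09, and adjusted p = 0.667 with an estimated correlation), as did exocrine pancreas (1.46, adjusted p = 0.00103, and adjusted p = 0.733 with an estimated correlation). The proteasome (0.14, adjusted p = 0.000744) and endoplasmic reticulum genes (0.07, adjusted p = 0.029) did too, each with adjusted p = 0.733 with an estimated correlation. Stromal markers moved downwards, with anxa4 the 1 of 22 past and 4 adjusted over the list alone (median -0.29, adjusted p = 0.000561, and adjusted p = 0.448 with an estimated correlation). Ribosomal proteins did as well, with 0 of 73 past in both counts (-0.06, adjusted p = 0.0023, and adjusted p = 0.733 with an estimated correlation). The 21 lists not called had adjusted p values of 0.0786 or more. Each of adh5, anxa4, cirbpb, ctdsp2, fbp1a, mdh1aa and ppm1la lost its call in 6 to 9 of the 10 fits that left out 1 fish, with a highest adjusted p of 0.138. The endoplasmic reticulum list lost its call in 6 of 10 such fits (highest 0.351), and the ribosomal list without female fish 8 (0.0702). Without male fish 11, 52 and 66, which share the model's spread, anxa4 (adjusted p = 0.0512), ctdsp2 (0.0532) and ppm1la (0.054) did not pass. With only the 2 female groups in the fit these genes (0.0892, 0.0855 and 0.094) and mdh1aa (0.0915) did not pass either.

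The effect of 25% carbohydrate was also tested in males. Slc13a5a, of the sodium-coupled citrate transporter family, rose by 2.82 ± 0.22 (adjusted p = 1.79e-05, 3 and 4 fish): the 3 males on 25% lay between 5.46 and 6.09, and no other array exceeded 3.49. The values on 0% were thus below the array medians and not shown to be above background, so the size of the rise is not exact. Among the named genes, chaperones of the endoplasmic reticulum rose next: hspa5 (BiP) by 2.61 ± 0.36, hsp90b1 by 2.59 ± 0.37, hyou1 by 2.25 ± 0.36 and pdia4 by 1.73 ± 0.29. For each of these 4 genes all 3 fish on 25% lay above all 4 on 0%. In females they stood higher on 25% as well without passing: hspa5 at 1.05 ± 0.30 (adjusted p = 0.102, all 5 fish on 25% above all 5 on 0%), hsp90b1 at 0.79 ± 0.30 (0.277), hyou1 at 0.76 (0.282) and pdia4 at 0.72 ± 0.24 (0.194). None of the 4 passed the interaction test (adjusted p = 0.275, 0.156, 0.318 and 0.568), so a difference between the sexes was not shown for them, and averaged over the sexes all 4 passed (highest adjusted p 0.00506). Of 70 genes on the endoplasmic reticulum list 8 rose (15 adjusted over the list alone), with a median of 0.36 (adjusted p = 9.46e-21, and adjusted p = 0.22 with an estimated correlation). Btg1, a brake on cell proliferation, fell by 0.99 ± 0.16, the ferritin gene fthl30 by 0.75 ± 0.13 and ing3, a chromatin reader, by 0.73 ± 0.13.

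**Figure D3:**
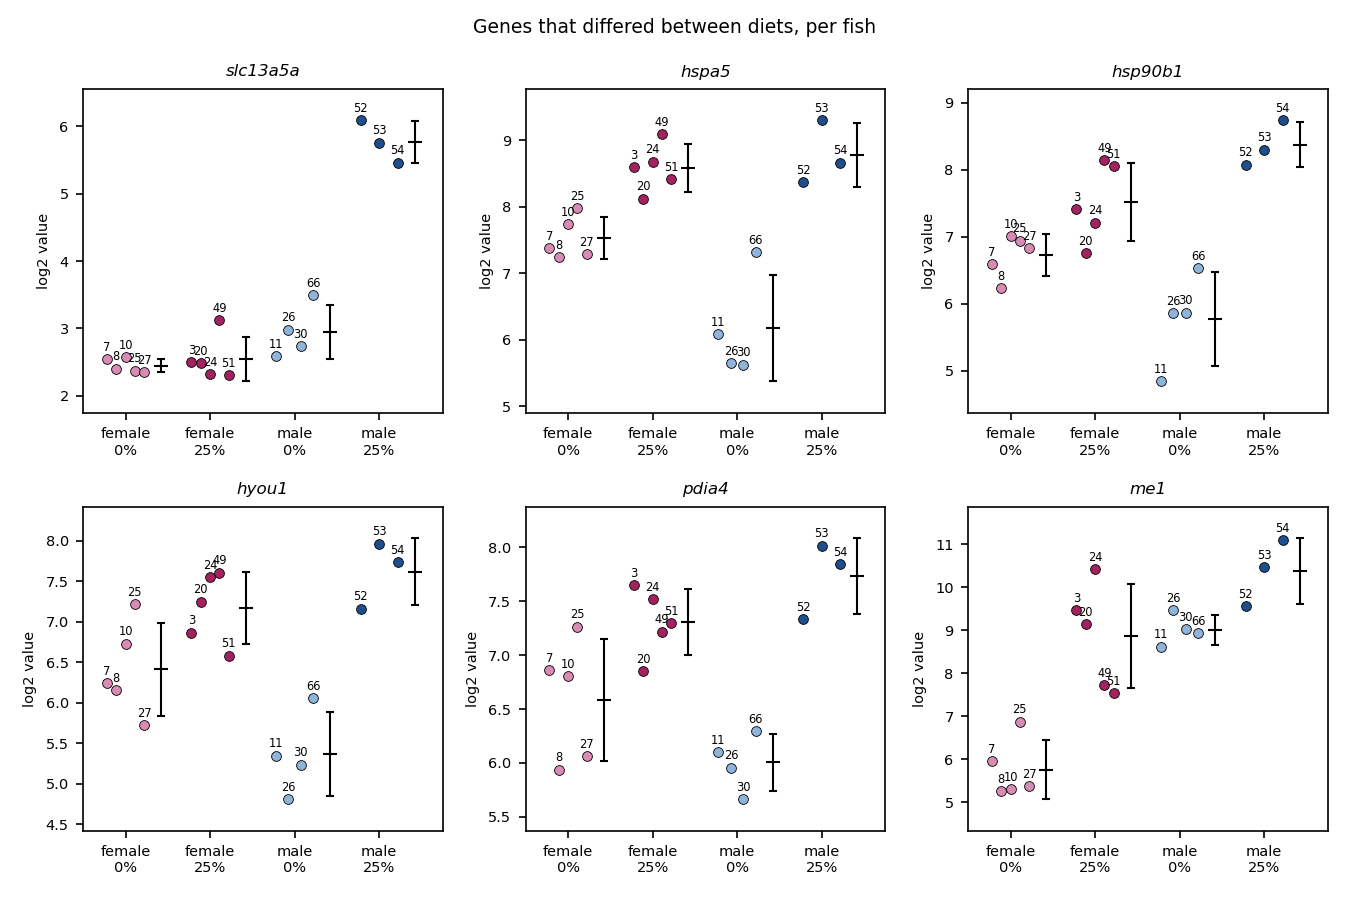
Log2 values of slc13a5a, hspa5, hsp90b1, hyou1, pdia4 and me1 for each fish (points, with fish numbers) by group, with black bars for the group mean ± SD. Slc13a5a lay at 5.46 to 6.09 in the 3 males on 25% and at or below 3.49 in every other fish.

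In males 18 probe sets passed, 15 higher and 3 lower, and 1268 had an unadjusted p under 0.05. Without any difference, a share of 0.05 of the 15502 probe sets would have such a p on average. The male fish on 25% had a fatty acid oxidation median of 0.59 with 0 of 29 past and 5 adjusted over the list alone (adjusted p = 3.62e-06, and adjusted p = 0.477 with an estimated correlation). Their oxidative phosphorylation median was 0.24 with 0 of 90 past in both counts (adjusted p = 3.34e-11, and adjusted p = 0.477). On the fatty acid oxidation list male fish 11 (0%) averaged 6.593, against 7.106 to 7.475 in the other males on 0%. That fish enlarges the difference, though the list's camera call held without it. Exocrine pancreas markers had a median of -1.39 (adjusted p = 0.000412, and adjusted p = 0.679 with an estimated correlation). Amino acid catabolism had -0.18 (adjusted p = 0.00106, and adjusted p = 0.679) and stromal markers -0.27 (adjusted p = 0.00181, and adjusted p = 0.477). Upward shifts were also called for the proteasome (0.13, adjusted p = 0.00171, and adjusted p = 0.679 with an estimated correlation) and muscle (0.37, adjusted p = 0.00615, and adjusted p = 0.679). The same held for red blood cells (0.30, adjusted p = 0.0133, and adjusted p = 0.719 with an estimated correlation) and heat shock (0.17, adjusted p = 0.0389, and adjusted p = 0.477). No list held its call with an estimated correlation, and the 19 lists not called had adjusted p values of 0.107 or more. Esr1 stood at 0.05 ± 0.21 (adjusted p = 0.989) and pck1 at 2.63 ± 1.09 (adjusted p = 0.522).

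The male count was 8 without fish 11, 7 without fish 26, 5 without fish 30, 39 without fish 66, 52 without fish 52, 1 without fish 53 and 4 without fish 54. With only the 2 male groups in the fit limma called 0 probe sets, and 971 had an unadjusted p under 0.05. Slc13a5a stood there at 2.82 ± 0.25 (adjusted p = 0.0747), hspa5 at an adjusted p of 0.274 and hsp90b1 at 0.204, and none of the other male genes named as risen or fallen passed. Slc13a5a passed in all 7 fits that left out 1 male, and hspa5 and hsp90b1 lost their calls without fish 53 or 54 (highest adjusted p 0.0792 and 0.0973). Hyou1 and pdia4 lost theirs in 5 of 7 (0.13 and 0.161), without fish 11, 26, 30, 53 or 54. Btg1 lost its call without fish 11, 26, 53 or 54 (0.123), ing3 in 6 of 7 fits (0.163) and fthl30 in 7 of 7 (0.165). Without fish 52 the muscle list turned (0.2), and amino acid catabolism (0.716) and the proteasome (0.618) lost their calls. Exocrine pancreas lost its call without fish 11, 66 or 54 (highest 0.572), red cells without 30 or 54 (0.572), stromal markers without 11 or 54 (0.138) and heat shock without 11, 26, 52 or 53 (0.218). Without fish 11, 52 and 66 together 28 probe sets passed, and slc13a5a was at 2.75 ± 0.22 and hspa5 at 3.35 ± 0.31. There pdia4 (adjusted p = 0.0511), btg1 (0.0627), ing3 (0.221) and fthl30 (0.221) did not pass, nor did the exocrine pancreas (0.515), proteasome (0.766) and heat shock (0.161) lists, and the muscle list turned (0.844).

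Whether the diet acted differently in the sexes was tested with the interaction. Relative to the male difference, the egg coat genes zp3.1 and zp3a.1 rose more in females, by 3.11 ± 0.64 and 3.03 ± 0.53. So did tmsb5 by 3.30 ± 0.56, the claudin gene cldnd by 3.29 ± 0.59 and mpv17 by 3.07 ± 0.66. Cyclins ccnb1 at 2.53 ± 0.39, ccna1 at 2.27 ± 0.36 and ccnb2 at 1.94 ± 0.32 went the same way, as did the germ granule gene tdrd7a at 0.56 ± 0.09. Tdrd7a lay below the array's median on all 17 arrays and was not shown above background in any fish. Male values lay below it on 7 of 7 arrays for tmsb5, mpv17 and zp3a.1, 5 of 7 for ccnb2 and 4 of 7 for ccnb1, so the male difference behind these sizes was not measured above background. Slc13a5a was the 1 probe set with a larger rise in males (-2.73 ± 0.28, adjusted p = 0.00101), with all 10 females below the array's median. Of 17 ovary markers 9 passed (14 adjusted over the list alone; median 2.01, adjusted p = 2.75e-29, and 0.0378 with an estimated correlation). Of 44 cell division genes 4 passed (16 higher and 1 lower adjusted over the list alone; adjusted p = 1.27e-15, and adjusted p = 0.0854 with an estimated correlation). Endoplasmic reticulum genes had a median of -0.32 with 0 of 70 past and 3 lower adjusted over the list alone (adjusted p = 1.3e-10, and adjusted p = 0.45 with an estimated correlation).

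In the interaction 108 probe sets passed, 107 of them towards females, and 9 lists passed. Exocrine pancreas had a median of 2.83 (adjusted p = 3.75e-09, and adjusted p = 0.707 with an estimated correlation). Muscle stood at -0.69 (adjusted p = 0.000286), red cells at -0.50 (adjusted p = 0.000649) and fatty acid oxidation at -0.32 (adjusted p = 0.00825), each with adjusted p = 0.743 with an estimated correlation. Medians were 0.16 for amino acid catabolism (adjusted p = 0.0263, and adjusted p = 0.792 with an estimated correlation) and -0.05 for ribosomal proteins (adjusted p = 0.0457, and adjusted p = 0.963). The count was 52 without female fish 7, 163 without 8, 53 without 10, 55 without 27 and 69 without 24. It was 65 without male fish 11, 47 without 26, 47 without 30, 57 without 66, 53 without 52, 43 without 53 and 52 without 54. Without fish 11, 52 and 66 together it was 15, with 7 towards females, 8 towards males and 5 of the 108 kept, so the majority towards females was not kept in the count. That fit held fewer males, so calls lost in it can reflect lower power. Slc13a5a passed there, and the other named genes that passed the interaction test did not (tmsb5 adjusted p = 0.132, ccnb1 0.112). Nor did the lists of muscle (0.287), fatty acid oxidation (0.558), amino acid catabolism (0.154) and ribosomal proteins (0.978). The other 5 lists, ovary and cell division among them, kept their camera calls. Mpv17 and zp3.1 lost their calls in 14 of the 17 fits that left out 1 fish (highest adjusted p 0.146 and 0.114), cldnd without male fish 52, 53 or 54 (0.0575) and zp3a.1 without male fish 54 (0.0525). Lists that lost their calls were muscle (0.942, turned) without male fish 52, red cells without male fish 54 (0.0838), and fatty acid oxidation without male fish 11, 66 or 54 (0.229). So did amino acid catabolism and ribosomal proteins in 7 and 8 of 17 fits (0.942 and 0.37).

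Averaged over the sexes, 296 probe sets differed with the diet, 226 higher and 70 lower on 25%. Endoplasmic reticulum genes rose in 12 of 70 cases (14 adjusted over the list alone; adjusted p = 4.79e-12, and adjusted p = 0.34 with an estimated correlation). Oxidative phosphorylation genes rose in 5 of 90 (28 higher and 1 lower adjusted over the list alone; adjusted p = 1.11e-13, and adjusted p = 0.385 with an estimated correlation). Ovary markers rose in 9 of 17 cases (13 adjusted over the list alone; adjusted p = 1.11e-13, and adjusted p = 0.34 with an estimated correlation). Their median was 2.05 in females and -0.04 in males (adjusted p = 0.555). The count was 191 without female fish 27, 187 without male fish 11, 121 without male fish 53, 161 without male fish 54 and 146 without fish 11, 52 and 66.

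The diet differences of the 2 sexes were also compared with each other across probe sets, which are not independent replicates. Pearson's correlation was 0.236 (exact two-sided p = 0.0571, 2 of the 35 splits of the males) and Spearman's was 0.309 (exact two-sided p = 0.0286, the smallest that 35 splits allow). Called in both sexes were 4 probe sets, against 0.38 for unrelated lists, each with the same sign. They were ing3 (-0.70 ± 0.10 in females and -0.73 ± 0.13 in males), btg1 (-0.64 ± 0.13 and -0.99 ± 0.16) and 2 without a gene name, all 4 singled out after their values were seen. Both contrasts share each probe set's spread in the single fit, so 0.38 is not an exact expectation. With only the 2 male groups in limma's fit 0 probe sets passed in males (ing3 adjusted p = 0.257, btg1 0.238). Of the 295 probe sets called higher in females 103 had a positive difference in males, and of the 30 called lower 28 had a negative one. In the other direction, all 18 probe sets called in males had the same sign in females.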

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

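Tests chosen only after the result was seen were those of esr1, of the intestinal markers with and without quantile normalization, of the pancreas covariate, and of the splits for diet in males, diet over sexes and the interaction. A fish lay far from the others of its group in 22 of 339 group tests, in 4 of 87 for list means and in 18 of 252 for named genes; chance marks about 1 in 20 groups.

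Ovary transcripts rose with the diet in females. Esr1 did not rise with them: the upper 95% bound of its difference was -0.142, without adjustment, whereas limma's adjusted p was 0.204. This test was chosen after the difference was seen and rests on 1 gene, so it does not decide whether oestrogen signalling was higher. By the rule set beforehand it stayed undecided whether ovary or oocyte RNA lay in the liver samples. Among females on 0% alone, 282 other risen probe sets followed the ovary mean with a median slope of 0.475. That lay just under the preset bound of 0.5 (exact one-sided p = 0.00833, the smallest that 120 orders allow). With 1 fish left out the median slope was 0.458 to 0.547. Of the 282 probe sets 267 had a positive slope, while the median slope over all probe sets was -0.0137. The fallen probe sets had a slope of -0.0564 (exact one-sided p = 0.225). Oocyte RNA carried over with the tissue may account for much of the rise, and a response of the liver itself cannot be told apart from it.

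Male fish 11, 52 and 66 lay apart from the other 4 males. Intestinal tissue in the samples is a candidate source: 13 of 16 markers exceeded every other array by at least 1 log2 unit in at least 1 of the 3 fish, with fabp2 at 11.20, 12.23 and 11.68 against at most 6.12 elsewhere. Fish 11 alone carried fabp6 at 12.13, and 1 of the 16 markers exceeded 5 on all arrays. Array scaling is argued against by array medians that spanned only 0.09. After quantile normalization 12 markers did so, which adds little, since that step keeps the order of values within an array. Both counts describe fish already seen to be high on this list. No biological explanation was tested.

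Camera called an upward shift of the endoplasmic reticulum list in males on 25%, with 8 of 70 genes past. The call was not kept with an estimated correlation (adjusted p = 0.22). Intestinal tissue does not account for the shift alone, since without the 3 males the list's median difference was 0.371 (list mean 0.65 ± 0.18), with 2 males left per diet. Exocrine pancreas RNA is argued against as the whole cause, since with its marker mean as covariate the median was 0.309 (list mean 0.56 ± 0.14) and the pancreas mean moved by -1.28. In males a response to the diet may remain, as a hypothesis that rests on 3 fish against 4. The female list mean was 6.739 (SD 0.212) on 0% and 6.892 (SD 0.187) on 25%. Hspa5 lay between 7.242 and 7.976 in females on 0% and between 8.118 and 9.09 on 25%. In females alone hspa5, hsp90b1, hyou1 and pdia4 did not pass, and averaged over the sexes they did.

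Other splits of the same fish were fitted to see whether chance could give as many calls. Chance is unlikely to give as many calls for sex (2106 against at most 163 in other splits, 1 of 100 as large), sex at 0% (516 against 65, 1 of 100), sex at 25% (761 against 9, 1 of 56) and diet in females (325 against 4, 1 of 100). The real grouping is itself 1 of these splits, so no smaller share was possible, and shares were not adjusted over the contrasts. Splits that mix groups put real differences into the spread, so their counts do not tell how many calls are false. For diet over sexes (296 against 462) and the interaction (108 against 461) chance is less firmly set aside. There 4 of 100 splits drawn from 8820 called as many, which a sample of that size does not set apart from 5 of 100. The other splits that called more all put fish 11, 52 and 66 together. For diet in males chance cannot be excluded (18 against 1014, 4 of 35), and the split with 1014 also groups those 3 fish, which points to a structure of the samples.

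The 3 males on 25% were not tested for such values, so none of them could be listed. In that group fish 52 had muscle markers at 6.005, against 4.17 and 4.085 in fish 53 and 54. In the groups tested, single values far from their group were these. Fish 49 (female, 25%) had leukocyte markers at 6.18 against 4.58 to 4.92, cyp2k6 at 8.31 and slc13a5a at 3.12. Fish 7 (female, 0%) had muscle markers at 4.72 and hbba2 at 8.16. Fish 10 (female, 0%) had cholesterol synthesis at 4.62 and pck1 at 5.31, and fish 27 had xenobiotic enzymes at 5.52. Fish 25 (female, 0%) had nots at 10.13 and cyp2k22 at 6.11. Fish 24 (female, 25%) had hbae3 at 4.75, vtg2 at 13.05 and psmd13 at 6.19, fish 3 had per2 at 6.79 and fish 51 had ccnb2 at 6.67. Fish 11 (male, 0%) had hsd11b2 at 4.64 against 6.91 to 7.34, cd59a at 3.27 against 8.16 to 8.98, tdrd7a at 2.84 and zpax1 at 3.36. Fish 26 (male, 0%) had hsp90ab1 at 11.32, and fish 30 had zp3a.1 at 3.15 and tpi1b at 9.93.

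The diet difference differed between the sexes by the interaction test for 108 probe sets. Named genes were tdrd7a at 0.56, tmsb5 at 3.30, slc13a5a at -2.73, ccnb1 at 2.53, zp3a.1 at 3.03, mpv17 at 3.07, ccna1 at 2.27, cldnd at 3.29, ccnb2 at 1.94 and zp3.1 at 3.11. List medians were 2.01 for ovary, 2.83 for exocrine pancreas, -0.50 for red cells, -0.69 for muscle, -0.32 for fatty acid oxidation, 0.16 for amino acid catabolism, -0.048 for ribosomal proteins, -0.32 for endoplasmic reticulum and 0.41 for cell division. With an estimated correlation only the ovary list kept its call, and the muscle list turned without male fish 52.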

How the results depend on the processing

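Of the named genes under quantile normalization, 55 for sex, 19 for diet in females, 8 for diet in males and 10 for the interaction kept direction and side of the threshold, and 8, 1, 2 and 2 lost their calls. Under trend and robust settings 59, 18, 7 and 12 kept them. For the results below the cause was not tested except where stated. Settings without fish 11, 52 and 66 and those with marker covariates were chosen after seeing the data. Without those 3 males the counts were 304 for sex at 0%, 28 for diet in males, 146 for diet over sexes and 15 for the interaction. With the ovary marker mean as covariate they were 9 for sex, 123 for sex at 0%, 3 for sex at 25% and 0 for diet in females, diet over sexes and the interaction. With the 3 marker means they were 11, 175, 2, 0, 1 and 0. In limma's 0 counts, 417, 627 and 455 probe sets had an unadjusted p under 0.05 with the ovary mean, and 389 for females and 390 for the interaction with the 3 means. Each of these counts lay below a share of 0.05 of the 15502 probe sets, which no difference at all would give on average. The ovary mean followed sex and diet in these fish. For me1 the standard error grew, as the diet difference in females went from 3.10 ± 0.50 to 2.89 ± 1.24. For some other genes the difference itself turned, as listed below. With only the groups compared, sex at 0% gave 337, sex at 25% 394 and diet in males 0 (971 unadjusted). Array weights gave 40 for diet in males and 64 for the interaction. Lists called with an estimated correlation, then with fry, were 1 and 9 for sex, 1 and 2 for diet in females, 0 and 1 in males, and 1 and 2 for the interaction. Quantile normalization gave 5 for females, and the ovary and 3-mean covariates gave 10 and 10 for sex and 3 and 4 for females. The sex comparison without the 3 males turned the intestine (adjusted p = 0.597) and muscle lists (0.764). The ovary covariate turned intestine (0.733), stroma (0.678) and muscle (0.966) and, for diet in females, stroma (0.928) and oxidative phosphorylation (0.434). The 3 means turned intestine (0.952), stroma (0.715) and muscle (0.979), the proteasome in females (0.492) and exocrine pancreas in males (0.989). Diet in males without the 3 turned muscle (0.844). The muscle list ranged over 2.07e-06 to 0.2 for diet in males and 3.68e-08 to 0.942 for the interaction when 1 fish was left out, turning without fish 52. Genes turned by the ovary covariate, then by the 3 means, were zp2.6 for sex (-0.285, -0.323) and diet (-1.10, -1.24), zpax1 (-0.25, -0.416), mpv17 (-0.351, -0.536) and zp3.1 (-0.363, -0.354). The 3 means also turned ctss2.1 (-0.159) and cldnd (-0.106). Leaving out 1 fish gave 275 to 447 for sex at 0%, 1 to 52 for diet in males, 121 to 377 for diet over sexes, 43 to 163 for the interaction and 0.173 to 0.268 for agreement, which was 0.309 by Spearman. Pseudocount alternatives did not apply because values are log. Dim probe sets were not shown to be above background, so the sizes of their differences are not exact.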

Other observations

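Marker lists of other tissues also varied between fish of one group. Exocrine pancreas markers averaged 8.01 (SD 1.07, n = 5) in females on 0%, 9.30 (SD 1.19, n = 5) on 25%, and 9.44 (SD 2.04, n = 4) and 8.17 (SD 1.73, n = 3) in males on 0% and 25%, and 14 of the 20 exceeded 5 on all arrays. Of the ovary list 0 of 17 members exceeded 5 on all arrays and 11 did on some; 0 of them belonged to another list, and 1 exocrine and 1 endoplasmic reticulum marker did.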
